A study of Mus musculus with 6 samples.

How the data were processed

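Total RNA was extracted with a column kit from Min6 cells that had received a lentiCRISPR v2 vector with a gRNA against Rosa26 or JunD, and Illumina libraries were prepared, per the labels' protocols. The deposited values are raw counts per gene, 1 table for each of the 6 libraries, with 53379 gene identifiers in the same order. TopHat2, featureCounts and the mm10 build are named in the submitters' processing notes. The versions, the annotation release, the strand setting, the library kit and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and counts of genes with near-identical copies are uncertain.

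Gene symbols were taken from a table of Ensembl identifiers, matched without the version number for 53274 of the identifiers (50604 matched with it). Coordinates, exon numbers, GC content and transcript length came from GENCODE release M21 on GRCm38, the assembly that mm10 names. Groups and replicate numbers came from the sample titles and the gRNA label. Totals ran from 41071566 to 50024931 counts per library, and no pair of libraries agreed within sampling noise in a chi-square comparison of their counts (chi-square per degree of freedom of 3.22 or more). CPM in the text are counts divided by the library's total, and intervals and SDs are over libraries.

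The comparison of JunD gRNA with Rosa26 gRNA used edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, a quasi-likelihood fit with the group as the sole term, and two-sided p-values with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was derived as its absolute value over the square root of the quasi-likelihood F statistic, and is approximate. Low counts bound the precision of genes near 1 CPM more than that of abundant ones. A set of 29 gene lists with 705 entries, of which 704 matched a gene, was fixed before the data were examined. They cover the AP-1 family and its linked genes, beta-cell function, stress, death, inflammation, metabolism, cell cycle, RNA quality and markers of other cell types. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 29 lists, and again with the correlation estimated and with the fry rotation test. Camera asks whether a list's genes rank apart from other genes, and fry whether they move one way on balance. With the correlation estimated, camera gave larger p-values even for lists whose estimate was no higher than the preset. That variant therefore does not isolate the effect of correlation between genes.

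Genes were named by a rule fixed at the same time. It took Jund, then the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 2 CPM, groups that do not overlap and an established symbol, then up to 4 members of each list with the smallest p, and 11 fixed genes of insulin production, stress and AP-1. With 0 genes eligible on 6 libraries, the rule was applied to the fit on 5. Genes outside it are said to have been chosen after their values were seen.

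Alternatives fixed beforehand were other normalizations, DESeq2 1.42.0, limma-voom, no or a stricter count filter, the replicate number as a block, each library left out in turn, the 10 most abundant genes left out, and stricter thresholds. Alternatives added after the data were seen were a correction for GC content and transcript length, voom with sample weights, DESeq2 without the earlier count filter, removal of 10 structural RNA and other genes, and other tools and normalizations on the 5 libraries. The correction fitted each library's log2 deviations by splines with 5 degrees of freedom.

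The procedure was tested on simulated counts, with 200 genes changed and the genes of 1 further list raised, whose calls count as true. Rosa26 gRNA replicate 1 kept its own mean profile, and the other 5 libraries shared a pooled one. Systematic differences among those 5, such as their trends with GC content, were absent, so the figures may be optimistic. With all 6 libraries edgeR recovered 0% of genes changed 1.25-fold, 30.6% at 1.5-fold, 62.0% at 2-fold and 77.1% at 3-fold among 17470 genes, with 0 false calls of 83. On the 5 libraries it recovered 53.1%, 74.0%, 76.0% and 89.8% among 17625 genes, with 10 false calls of 174. No file or sample was left out of the main comparison. Results of some single genes in the fixed lists are not reported here.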

Results

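RNA abundance was measured by RNA-seq in Min6 cells, a mouse insulinoma line used as a model of the pancreatic beta cell. The cells carried a lentiviral CRISPR-Cas9 vector with a guide RNA (gRNA) against Jund, which encodes a member of the AP-1 family of transcription factors, or against the Rosa26 locus as the negative control. There were 3 libraries per group, all from cells at passage 28, harvested 8 days after transduction and after 30 hours of glucolipotoxic conditions, a metabolic stress of high glucose and fatty acid. No library without this stress was analysed here. Counts assigned to genes came to 43408459, 50024931 and 47834207 in the Rosa26 gRNA libraries and to 41803921, 41071566 and 49628813 in the JunD gRNA libraries. The labels do not say whether replicates came from separate transductions, so p-values measure the spread between these samples, which may be technical. The comparison asks which transcripts differ in stressed beta cells after targeting of Jund.

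Jund was lower in each of the 3 JunD gRNA libraries than in any Rosa26 gRNA library. Its level was 34.7 ± 4.46 CPM (read count scaled to the library total, SD, n = 3) with the Rosa26 gRNA and 24.8 ± 2.15 CPM (SD, n = 3) with the JunD gRNA. The counts behind these levels were 1706, 1727 and 1454 against 944, 1029 and 1333. Its log2 fold change over all 6 libraries was -0.47 ± 0.11 (SE), which did not pass the test across genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.417). Without Rosa26 gRNA replicate 1, a library that stood apart from the rest, it was -0.38 ± 0.08 (SE) and passed (adjusted p = 0.00773). The gene (ENSMUSG00000071076.6) lies on chromosome 8 from 70698949 to 70700616, on the plus strand of GRCm38 (mm10), and has 1 annotated exon. The antisense gene Gm11175 overlaps it and had 0 counts in all 6 libraries. The gRNA's target position is not given in the sources used here, and a count of reads over the gene does not report whether its DNA was edited.

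Inflammatory and NF-kB response genes were lower as a group in the JunD gRNA libraries, and beta-cell identity and nuclear oxidative phosphorylation genes higher, by a gene set test with a preset correlation of 0.01 between genes (camera). With all 6 libraries none of these 3 lists passed with an estimated correlation (adjusted p = 0.145, 0.505 and 0.505) or in the fry rotation test (0.0644, 0.099 and 0.192). Without Rosa26 gRNA replicate 1 the inflammatory list passed fry (0.0412). With all 6 libraries the estimated correlation was 0.0112 for the inflammatory list, close to the preset, yet its unadjusted camera p went from 1.37e-08 to 0.005. A higher correlation between its genes therefore does not account for that loss. The estimates for the beta-cell identity and oxidative phosphorylation lists were 0.0495 and 0.306. The median log2 fold change of these 3 lists was -0.25, 0.12 and 0.15 respectively with all 6 libraries, and -0.16, 0.06 and 0.09 without Rosa26 gRNA replicate 1. Among their members, the log2 fold change was -1.48 ± 0.18 (SE) for the chemokine gene Ccl2 and -0.57 ± 0.09 for the growth factor gene Csf1, and 0.58 ± 0.12 for Mafa and 0.34 ± 0.07 for Pdx1, both transcription factors of the beta cell; in each of these 4 genes the 3 libraries of one group lay apart from those of the other. No single gene passed in edgeR with all 6 libraries, where 0 of 17767 genes were higher and 0 lower at an adjusted p under 0.05, and 2119 had an unadjusted p under 0.05. The smallest adjusted p, 0.115, belonged to Ccl2, Ptgs2 and Steap4. limma-voom also called 0 genes, DESeq2 called 20 higher and 47 lower on the same genes and 17 higher and 31 lower without the earlier count filter, and edgeR without a count filter called 33 higher and 53 lower.

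Rosa26 gRNA replicate 1 differed from the other 5 libraries across the transcriptome. The first principal component held 45.8% of the variance and placed it at -62.1, with the others between 6.09 and 22.5. Its genes deviated from the mean of the other libraries by a median of 0.303 on the log2 scale, against 0.088 to 0.159 for the others. A set of 10 genes, chosen after the data were seen, took 1.67% of its counts and 0.174% to 0.227% elsewhere. The set held 4 structural RNA genes (the 7SK gene Rn7sk, the RNase P RNA gene Rpph1 and both mitochondrial rRNA genes), 3 genes annotated as microRNA, 2 as long non-coding RNA, and the protein-coding gene Lars2. The insulin gene Ins2 took 2.19% of its counts and 4.59% to 5.36% in the others. Across genes, which are not independent replicates, its deviations had a Spearman correlation of -0.506 with GC content. Such correlations were 0.299, 0.263 and 0.419 in the JunD gRNA libraries, and 0.105 and 0.0186 in Rosa26 gRNA replicates 2 and 3. With transcript length they were -0.151, -0.187 and -0.254 against -0.0878 and -0.0856. Rosa26 gRNA replicate 1 was part of the mean with which each of the other 5 was compared. No such correlation was computed without it. Among those 5 libraries both trends were nevertheless ordered by gRNA. The uncorrected comparison without Rosa26 gRNA replicate 1 therefore cannot tell the trends apart from the gRNA.

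**Figure D1:**
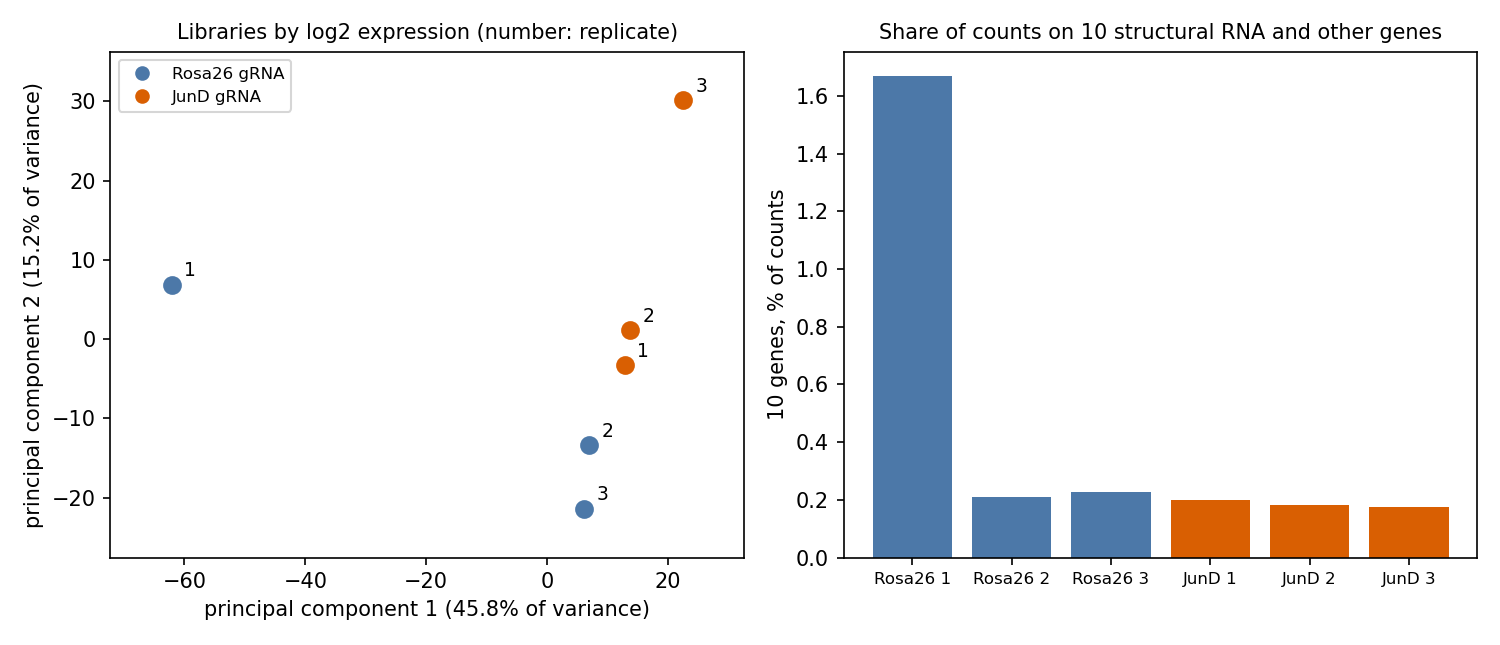
Left, the 6 libraries on the first 2 principal components of log2 CPM, with the replicate number beside each point; right, the percent of each library's counts on the 10 structural RNA and other genes. Rosa26 gRNA replicate 1 lies at -62.1 on the first component and has 1.67% of its counts on these genes, against at most 0.227% in the others.

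Without Rosa26 gRNA replicate 1, edgeR called 266 genes higher and 257 lower among 18296. Leaving out each library in turn was planned before the data were examined, but using this particular fit to name genes was decided afterwards, because the naming rule found 0 eligible genes with all 6 libraries and 460 without that library. Leaving out any other single library gave 0 calls. The changes were small, with a median absolute log2 fold change of 0.25 among the 523 called genes, and 16 of them reached an absolute value of 1. The left-out library lay on the same side of the JunD gRNA mean as the other Rosa26 gRNA libraries for 474 of the 523 (90.6%), compared with 68.1% of all tested genes. The groups did not overlap across all 6 libraries for 455 of them (87.0%). Both shares are raised by selecting the genes on 5 of these libraries. The 10% chance of no overlap for an unselected gene is therefore no reference for the 87.0%. A correction for GC content and transcript length, chosen after the data were seen, gave 331 higher and 189 lower on the 5 libraries, so the share of higher calls was 63.7% in place of 50.9%. In what follows, "rose" and "fell" refer to edgeR calls on these 5 libraries, and SE, derived from the F statistic, refers to the log2 fold change in that fit. None of the 523 passed in edgeR with its count filter on all 6 libraries, where 62 of them were called by DESeq2, 76 by edgeR without a count filter, 23 after the GC and length correction and 284 by limma-voom with sample weights, the last 2 settings chosen after the data were seen. Sample weights also made 4 lists higher and 9 lower with all 6 libraries, in place of 2 and 2.

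**Figure D2:**
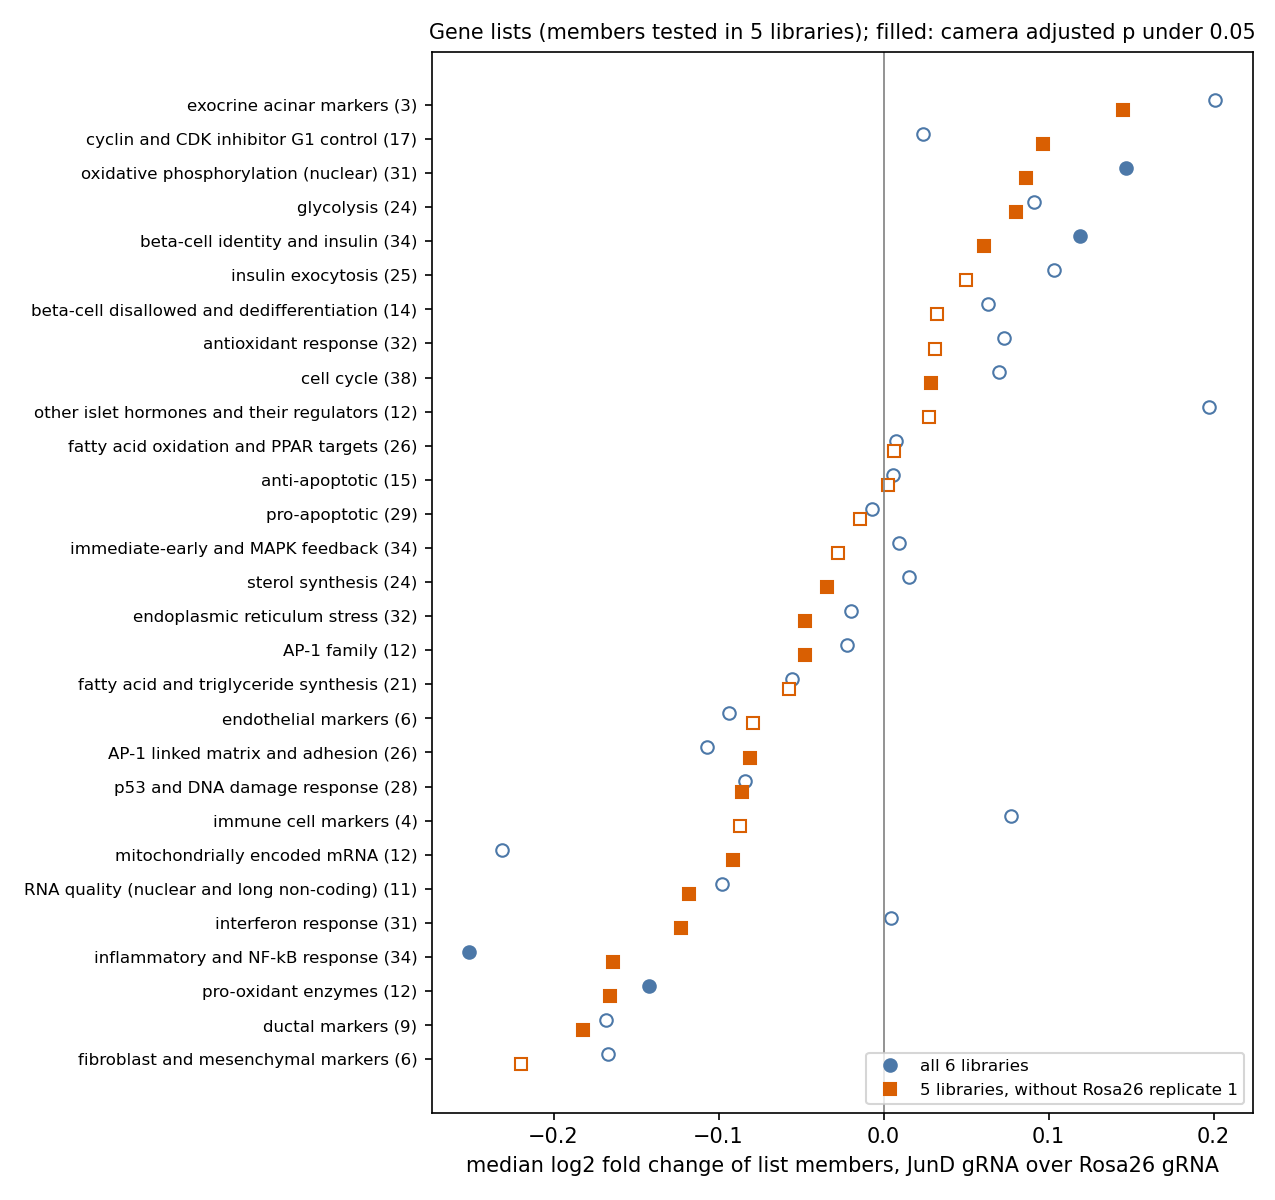
Median log2 fold change (JunD gRNA over Rosa26 gRNA) of the tested members of each of 29 gene lists, with all 6 libraries (circles) and without Rosa26 gRNA replicate 1 (squares); filled symbols have a camera adjusted p under 0.05 with the preset correlation. The inflammatory list lies at -0.25 and -0.16, and the nuclear oxidative phosphorylation list at 0.15 and 0.09.

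Of 34 tested inflammatory and NF-kB response genes, 8 fell, 0 rose and 26 did not pass. Adjusted over the list alone, 13 fell, and with all 6 libraries 10 fell. Ccl2, which encodes a monocyte-attracting chemokine, fell by 1.44 ± 0.17 (SE) on the log2 scale. Over all 6 libraries its level was 6.84 ± 0.924 CPM with the Rosa26 gRNA and 2.42 ± 0.461 CPM with the JunD gRNA (SD, n = 3 each), a log2 fold change of -1.48 (adjusted p = 0.115). Cxcl1, a neutrophil-attracting chemokine, fell by 1.71 ± 0.32, Csf1, the macrophage growth factor, by 0.63 ± 0.06, and Lcn2, which encodes lipocalin 2, by 0.92 ± 0.15. Lcn2 stood at 3.64 CPM in Rosa26 gRNA replicate 1, within the 3.13 to 4.35 CPM of the JunD gRNA libraries. Nos2, the inducible nitric oxide synthase, fell by 2.85 ± 0.51 but was at or below 1.12 CPM in every library. The other 3 that fell, chosen after their values were seen or named under another list, were Icam1 by 0.52, Cxcl10 by 0.45 and Birc3 by 0.39. The list was lower in camera with all 6 libraries (adjusted p = 3.97e-07) and with 5 (adjusted p = 1.04e-10). With an estimated correlation the adjusted p was 0.145 and 0.242. All 8 calls held after the GC and length correction on the 5 libraries.

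Pro-oxidant enzymes were lower as a list with all 6 libraries (camera adjusted p = 0.0149, adjusted p = 0.456 with an estimated correlation). The estimate was -0.0164, below the preset, so that loss does not come from a higher correlation between the genes. Of 12 tested members 2 fell and 0 rose, and 3 fell when adjusted over the list alone. The 2 were Nos2 and Ptgs2, and Ptgs2, the prostaglandin synthase COX-2, fell by 1.03 ± 0.12 (SE). Over all 6 libraries Ptgs2 stood at 10.6 ± 1.36 CPM with the Rosa26 gRNA and 4.84 ± 0.364 CPM with the JunD gRNA (SD, n = 3 each), a log2 fold change of -1.11. The list's call was lost with limma-voom (adjusted p = 0.118), without a count filter (0.186), with DESeq2 without the earlier filter (0.189), and without Rosa26 gRNA replicate 2 (0.0545), Rosa26 gRNA replicate 3 (0.0596) or JunD gRNA replicate 1 (0.121), and ranged from 0.00269 to 0.456 over its alternatives. Of 32 tested antioxidant response genes, Mt1, a metallothionein, rose by 0.22 and 2 fell. Mt1 stood at 101 CPM in Rosa26 gRNA replicate 1 and 255 to 318 CPM in the others, and its log2 fold change with all 6 libraries was 0.55 (adjusted p = 0.434). Gpx3, a secreted glutathione peroxidase, fell by 0.86 ± 0.07, and Slc7a11, the cystine transporter subunit, by 0.43 ± 0.07. Adjusted over the list alone, 9 rose and 2 fell, and the list did not pass with 6 (adjusted p = 0.0735, 0.687 with an estimated correlation) or 5 libraries (0.183). It passed as higher with limma-voom (0.0468), without a count filter (0.0296), with the replicate number as a block (0.036), with DESeq2 without the earlier filter (0.0255), with limma-voom on the 5 libraries (0.0409), and without Rosa26 gRNA replicate 2 (0.0328), Rosa26 gRNA replicate 3 (0.0268) or JunD gRNA replicate 1 (0.0498).

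Of 34 tested beta-cell identity and insulin genes, 9 rose, 3 fell and 22 did not pass. Adjusted over the list alone, 12 rose and 5 fell, and with all 6 libraries 2 rose. Pdx1, a transcription factor of beta-cell development and function, rose by 0.37 ± 0.04 (SE). Its level over all 6 libraries was 261 ± 15.8 CPM with the Rosa26 gRNA and 326 ± 10.2 CPM with the JunD gRNA (SD, n = 3 each), a log2 fold change of 0.34 (adjusted p = 0.417). Mafa, an activator of insulin transcription, rose by 0.47 ± 0.06, Nkx6-1 by 0.21 and the glucose transporter gene Slc2a2 by 0.29. Glp1r and Ins2 rose by 0.17 and 0.11, and Ins1 did not pass (0.02 ± 0.04, adjusted p = 0.898). Over all 6 libraries Ins2 and Ins1 had log2 fold changes of 0.40 (adjusted p = 0.466) and 0.26 (0.55), where Rosa26 gRNA replicate 1 had the lowest level of both. Insm1 (0.18) and Sytl4 (0.17) also rose, while Ero1lb, Iapp and Pcsk1 fell by 0.14, 0.11 and 0.12, and of these 5 genes Insm1, Sytl4, Iapp and Pcsk1 were named after their values were seen. With all 6 libraries the log2 fold changes of Slc2a2, Insm1, Sytl4, Ero1lb, Iapp and Pcsk1 were 0.19, 0.28, 0.10, -0.24, -0.01 and -0.20, and Rosa26 gRNA replicate 1 lay within or beyond the JunD gRNA range for Slc2a2, Sytl4 and Iapp. After the GC and length correction on the 5 libraries, Insm1, Ero1lb, Iapp and Pcsk1 were among the genes that no longer passed. The list was higher in camera with 6 (adjusted p = 0.00186) and 5 libraries (adjusted p = 7.85e-05), and had an adjusted p of 0.505 and 0.279 with an estimated correlation. Reads of Ins1 and Ins2, which have similar coding sequences, could be split between them by the counting.

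**Figure D3:**
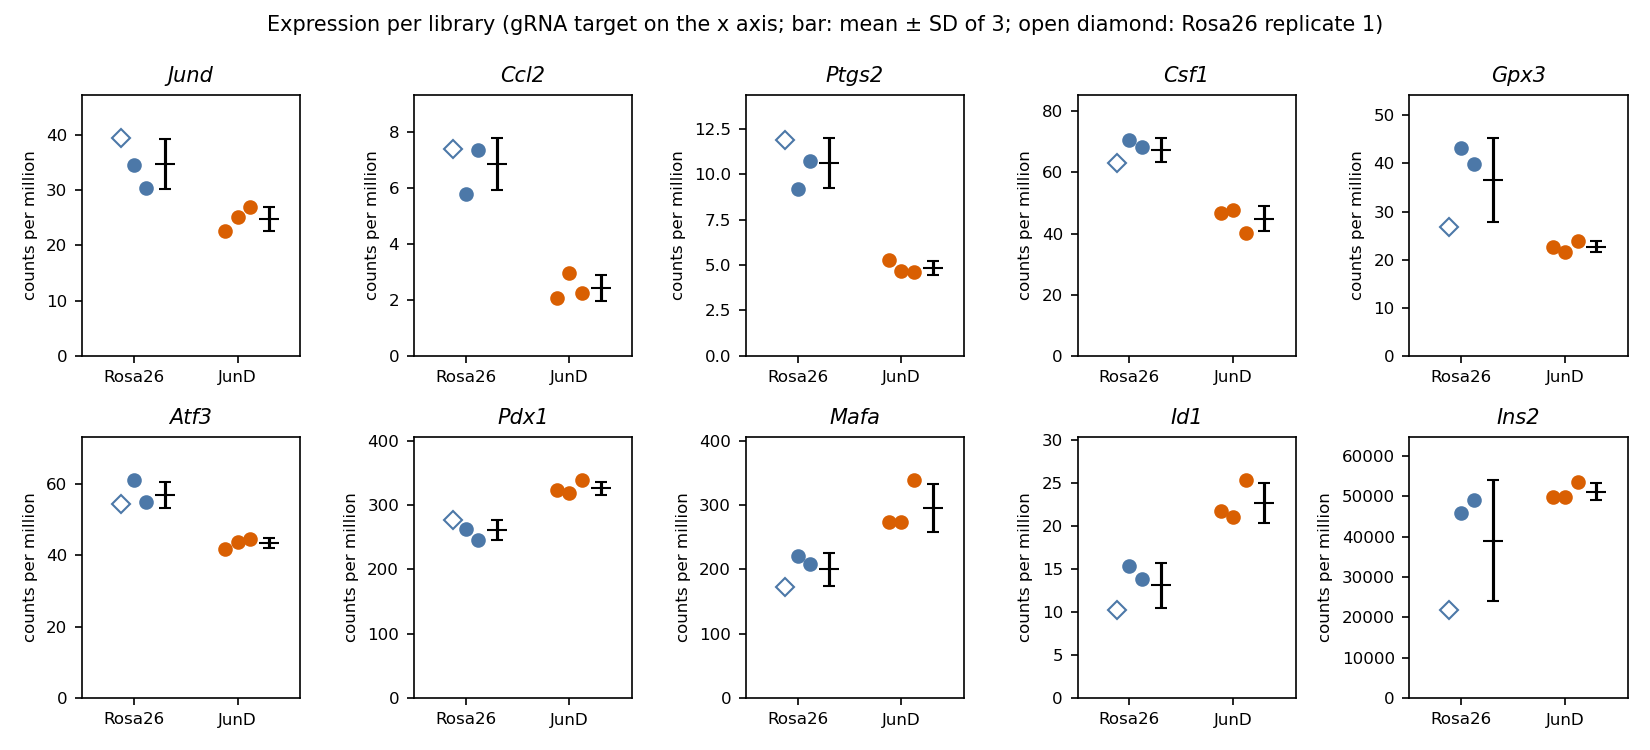
CPM of 10 named genes in each library, with the mean ± SD of 3 libraries beside the points and Rosa26 gRNA replicate 1 as an open diamond. Ccl2 averages 6.84 CPM with the Rosa26 gRNA and 2.42 CPM with the JunD gRNA, and Ins2 in Rosa26 gRNA replicate 1 (21900 CPM) lies below the other 5 libraries.

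Nuclear genes of oxidative phosphorylation were higher as a list without any single member passing. Of 31 tested members, 29 had a positive log2 fold change with 6 libraries and 29 with 5, and 0 passed over all genes or adjusted over the list alone. Ndufb10, a complex I subunit, had a log2 fold change of 0.16 ± 0.05 (SE) with 5 libraries and 0.27 ± 0.10 with 6, and its level was lowest in Rosa26 gRNA replicate 1 (62.4 CPM, against 76.1 to 90.7 CPM in the others). Camera gave an adjusted p of 1.62e-05 with 6 libraries and 1.91e-05 with 5, and 0.505 and 0.279 with an estimated correlation. After the GC and length correction on the 5 libraries the list was higher at the preset correlation (2.21e-07). Mitochondrially encoded mRNAs had a median of -0.09 and a mean of 0.03 on the 5 libraries and were called lower (camera adjusted p = 0.011, adjusted p = 0.428 with an estimated correlation). With all 6 libraries their median was -0.23 and their mean -0.07. Of 12 tested, mt-Nd4, mt-Nd1 and mt-Co1 fell by 0.17, 0.14 and 0.12, and 6 fell adjusted over the list alone. The log2 fold changes of mt-Nd4 and mt-Nd1 with all 6 libraries were -0.35 and -0.23. None of the 3 passed after the GC and length correction on the 5 libraries, where mt-Nd1 and mt-Co1 changed sign and the list did too (adjusted p = 0.0651). The glycolysis list, with 24 tested members, was higher with 5 libraries (camera adjusted p = 0.0412, adjusted p = 0.279 with an estimated correlation) and did not pass there after the GC and length correction (0.166). With 6 libraries the mitochondrial and glycolysis lists did not pass (0.116 and 0.149), but both did with sample weights (0.0188 and 0.0346) and with DESeq2 without the earlier filter (0.00218 and 0.0316), and the mitochondrial list also with DESeq2 (0.0194), limma-voom (0.0374), without a count filter (0.0296), with a stricter one (0.0143) and without Rosa26 gRNA replicate 2 (0.0418).

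Within the AP-1 family, Jund and Atf3, a stress-induced ATF factor, fell, and 10 of 12 tested members did not pass. Atf3 fell by 0.41 ± 0.06 (SE). Jun (-0.01 ± 0.06), Junb (0.09 ± 0.06), Fos (0.09 ± 0.06) and Fosl2 (0.02 ± 0.05) did not pass, and the signs of Jun, Junb and Fosl2 turned under some settings. The log2 fold changes of these 4 with all 6 libraries were 0.01, 0.15, 0.14 and -0.01. The list, which contains the targeted gene, passed as lower with 5 libraries (camera adjusted p = 0.0417, 0.428 with an estimated correlation) and not with 6 (0.197). It passed after the GC and length correction of the 6 (0.000506), with sample weights (0.0334) and without JunD gRNA replicate 3 (0.0425), and not with limma-voom on the 5 (0.0879). Adjusted over the list alone 2 fell. Of 26 tested matrix and adhesion genes linked to AP-1, 4 fell and 2 rose, and 5 fell and 3 rose adjusted over the list alone. Plau, the urokinase gene, fell by 0.82 ± 0.17, Spp1, which encodes osteopontin, by 0.51 ± 0.04, Itga2 by 0.49 and Cd44 by 0.33, whereas the keratin genes Krt8 and Krt18 rose by 0.22 and 0.21. Krt18 was named after its value was seen. It did not pass after the GC and length correction on the 5 libraries (log2 fold change 0.16, edgeR adjusted p = 0.0502). The list was lower with 5 libraries (camera adjusted p = 0.00903, 0.279 with an estimated correlation) and did not pass with 6 (0.138), where it passed after the GC and length correction (0.00271) and with sample weights (0.0334). Of 34 tested immediate-early and MAPK feedback genes, Atf3, Ptgs2 and Klf6 (-0.29) fell and 0 rose, with 5 each way adjusted over the list alone, and the list did not pass with 6 (0.97) or 5 libraries (0.178). After the GC and length correction on the 5 libraries the list passed as lower (0.00457) and Klf6 did not pass (adjusted p = 0.0571). The Klf6 log2 fold change with all 6 libraries was -0.49.

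Endoplasmic reticulum stress genes were lower as a list with 5 libraries (camera adjusted p = 0.0015, 0.317 with an estimated correlation) and not with 6 (0.424), where it passed after the GC and length correction (0.0311) and with sample weights (0.00239). Of 32 tested, 5 fell and 0 rose, and 11 fell and 2 rose adjusted over the list alone. The chaperone genes Hspa5 and Hsp90b1 fell by 0.12 and 0.16, Atf6 by 0.18, Ern1 by 0.14 (named after its value was seen), and Atf3 as above. Hsp90b1, Atf6 and Ern1 did not pass after the GC and length correction on the 5 libraries, and Hsp90b1 had a log2 fold change of -0.28 with all 6. Ddit3, which encodes the stress factor CHOP, did not pass (-0.02 ± 0.05, SE, adjusted p = 0.891) and changed sign with all 6 libraries (0.07). Txnip, a glucose-induced gene, had a log2 fold change of -0.05 ± 0.05 (adjusted p = 0.671), and of -0.01 with all 6. Of 29 tested pro-apoptotic genes 0 passed, with 1 higher adjusted over the list alone (camera adjusted p = 0.988 with 6 libraries, 0.48 with 5). Of 15 anti-apoptotic genes, Bag3 rose by 0.25 and Birc3 fell, with 2 higher and 1 lower adjusted over the list alone (0.97 and 0.815).

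Among the 20 genes ranked by fold change, 10 rose and 10 fell. Id1 and Id3, inhibitors of helix-loop-helix factors, rose by 0.64 ± 0.09 and 0.60 ± 0.08 (SE). Over all 6 libraries Id1 stood at 13.1 ± 2.65 CPM with the Rosa26 gRNA and 22.7 ± 2.3 CPM with the JunD gRNA (SD, n = 3 each), a log2 fold change of 0.80. Id2, named after its value was seen, rose by 0.34, and Inhba, an activin subunit gene named in the same way, fell by 0.56. The other 8 ranked genes that rose were AV356131, Ngb, Fam177a, Tm6sf1, Ecel1, Shh, Hs3st2 and Nkx6-2, between 0.62 and 0.95, and all averaged below 10 CPM in each group. Among the ranked genes that fell, beside those above, Steap4, a metalloreductase gene, fell by 1.36 ± 0.20, Lrrtm2 by 0.86, Neurl3 by 0.79, the complement gene C4b by 0.76 and Uts2b by 0.76. Nkx6-2 and Uts2b did not pass after the GC and length correction on the 5 libraries, where their log2 fold changes were 0.48 and -0.64 (edgeR adjusted p = 0.107 and 0.0686). Uts2b stood at 1.94 CPM in Rosa26 gRNA replicate 1, within the 1.77 to 2.52 CPM of the JunD gRNA libraries, and its log2 fold change with all 6 libraries was -0.50.

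Interferon response, p53 and DNA damage response and sterol synthesis genes were lower as lists with 5 libraries (camera adjusted p = 0.00903, 0.0321 and 0.0121; 0.279, 0.317 and 0.317 with an estimated correlation). With all 6 libraries the camera adjusted p was 0.665, 0.218 and 0.574, but 0.0334, 0.0328 and 0.0312 with sample weights, and 0.0154 for the p53 list after the GC and length correction. Of 31 interferon response genes, B2m and Rsad2 fell by 0.38 and 0.35 (1 higher and 2 lower adjusted over the list alone). B2m stood at 50.9 CPM in Rosa26 gRNA replicate 1, below the JunD gRNA libraries (52.5 to 53.7 CPM), and its log2 fold change with all 6 libraries was -0.24 (adjusted p = 0.433). Of 28 p53 response genes Trp53inp1 fell by 0.35 (2 each way over the list alone). Among 24 sterol synthesis genes, those that fell included Msmo1 and Cyp51, by 0.24 and 0.15 (4 lower over the list alone), and Cyp51 did not pass after the GC and length correction. Cell cycle genes and those of G1 control were higher as lists with 5 libraries (0.0462 and 0.0321, 0.356 and 0.317 with an estimated correlation) and not with 6 (0.305 and 0.424). The cell cycle list passed with 6 after the GC and length correction (0.025) and with sample weights (0.0476), and did not pass with 5 scaled by library totals (0.0649). Cdc20 rose by 0.21 among 38 cell cycle genes, 1 also over the list alone. Of 17 G1 control genes, Cdkn2c, Cdkn2d and Cdkn2a, which encode cell cycle inhibitors, rose by 0.23, 0.22 and 0.22 (6 over the list alone). After the correction on the 5 libraries Cdkn2d and Cdkn2a did not pass, with log2 fold changes of 0.18 and 0.12 (edgeR adjusted p = 0.0502 and 0.187). The G1 list's median (0.10) and mean (-0.01) with 5 libraries differed in sign, and with 6 they were 0.02 and -0.02.

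Lists of insulin exocytosis, other islet hormones, beta-cell disallowed genes, fatty acid oxidation, and fatty acid and triglyceride synthesis did not pass with 6 or 5 libraries. Their camera adjusted p was 0.424, 0.352, 0.856, 0.777 and 0.804 with 6 libraries and 0.164, 0.164, 0.725, 0.825 and 0.485 with 5. The islet hormone list passed as lower after the GC and length correction on the 5 libraries (0.0322). Of 25 exocytosis genes, Cplx2 and Rab27a rose by 0.21 and 0.16 and Syt4 fell by 0.26. Cplx2 and Syt4 had log2 fold changes of 0.10 and -0.43 with all 6 libraries, and Rosa26 gRNA replicate 1 lay within or above the JunD gRNA range for Cplx2 and Rab27a. Ppy, the pancreatic polypeptide gene, fell by 0.70 ± 0.08 (SE), but stood at 10.1 CPM in Rosa26 gRNA replicate 1 and 15.5 to 18.7 CPM with the JunD gRNA, and with all 6 libraries its log2 fold change was -0.35 (adjusted p = 0.602). Of 14 disallowed or dedifferentiation genes, Aldh1a3 rose by 0.35 and Igfbp4 and Cxcl12 fell by 0.38 and 0.31. Acly, ATP citrate lyase, rose by 0.10, and of 26 fatty acid oxidation genes 0 passed. Adjusted over the list alone, the counts higher and lower were 3 and 1 for exocytosis, 0 and 1 for islet hormones, 1 and 2 for disallowed genes, 0 and 0 for fatty acid oxidation, and 4 and 2 for fatty acid and triglyceride synthesis.

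Markers of other cell types were few among the tested genes. Fibroblast, immune and endothelial lists had 6, 4 and 6 tested members, 0 of them past the test over all genes, with camera adjusted p of 0.944, 0.699 and 0.385 on 5 libraries and 0.672, 0.939 and 0.732 on 6. Adjusted over the list alone 0 passed on 5 libraries and 1 on 6, the fibroblast marker Thy1 (log2 fold change 1.67 ± 0.45, SE, and at most 1.01 CPM in any library). The ductal list was lower with 5 libraries (camera adjusted p = 0.00903, 0.279 with an estimated correlation; 0.68 with 6). Of its 9 members Spp1, Prom1 and Epcam fell, the last 2 by 0.20 and 0.18, and Krt7 rose by 0.19, with 4 lower and 2 higher over the list alone. Prom1 and Epcam had log2 fold changes of -0.32 and -0.10 with all 6 libraries, and Epcam in Rosa26 gRNA replicate 1 (128 CPM) lay within the JunD gRNA range (126 to 134 CPM). The exocrine acinar list was higher with 5 libraries (0.011, 0.279 with an estimated correlation; 0.189 with 6 and 0.0229 without JunD gRNA replicate 2) on 3 tested members (2 with 6 libraries), none of which passed over all genes, and 2 passed over the list alone. Those 3 members had a median log2 fold change of 0.15 but a mean of 1.12, so 1 of them lay far above the median. The list of nuclear and long non-coding RNA, kept as a sign of RNA quality, was lower with 5 libraries (0.0412, 0.44 with an estimated correlation) and did not pass with 6 (0.424), or with 5 after the GC and length correction (0.619). Neat1 fell by 0.15 (3 lower over the list alone) and did not pass after that correction. The median, mean and camera direction of a list also differed in sign, with 6 libraries, for the immediate-early, anti-apoptotic, interferon, sterol, G1 control, fatty acid oxidation, fibroblast and immune lists, and with 5 for the anti-apoptotic, fatty acid oxidation, fibroblast, disallowed and islet hormone lists.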

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

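The correction for GC content and transcript length, sample weights in limma-voom, DESeq2 without the earlier filter, removal of 10 structural RNA and other genes and every other tool or scaling on the 5 libraries were chosen only after the data were seen; the cause of the changes below was not tested, except that the 5-library settings hold 1 library fewer.

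With all 6 libraries, 0 genes were called higher and 0 lower in edgeR (2119 at an unadjusted p under 0.05), and 0 also with relative log expression (RLE) factors, upper-quartile factors, library totals, the stricter filter, the 10 most abundant genes left out, those 10 structural RNA and other genes left out and limma-voom. DESeq2 called 20 higher and 47 lower, DESeq2 without the earlier filter 17 and 31, no filter 33 and 53, the GC and length correction 9 and 14, and sample weights 131 and 162, with a weight of 0.132 for Rosa26 gRNA replicate 1. With 1 library left out the counts ran from 0 to 266 higher and 0 to 257 lower, all calls coming without Rosa26 gRNA replicate 1. On those 5 libraries DESeq2 called 340 and 286, limma-voom 292 and 296, the GC and length correction 331 and 189, RLE 280 and 249, and library totals 244 and 270. Of the 523 edgeR calls on the 5 libraries, 442 were shared with DESeq2, 508 with limma-voom and 315 with the GC and length correction there, and with all 6 libraries 62 of the 67 DESeq2 calls and 23 of the 23 calls after the correction were among them, in the same direction. Genes under about 1 CPM are limited by their counts.

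Jund was lower under every setting run, from -0.774 to -0.378 on the log2 scale. It passed with DESeq2 (-0.468, adjusted p = 0.0427), no filter (-0.455, 0.0455) and sample weights (-0.412, 0.00722), and on the 5 libraries with edgeR (-0.38), DESeq2 (-0.378), limma-voom (-0.378), the GC and length correction (-0.541), RLE (-0.378) and library totals (-0.385); over all settings its adjusted p ran from 2.7e-05 to 0.774. With 1 library left out its log2 fold change ran from -0.545 to -0.38.

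Of the 29 lists, 2 were higher and 2 lower with all 6 libraries, and 0 and 0 with an estimated correlation or with fry. In fry the adjusted p was 0.0644 for the inflammatory list, 0.192 for nuclear oxidative phosphorylation, 0.099 for beta-cell identity and 0.0644 for pro-oxidant enzymes. On the 5 libraries 4 lists passed fry, the AP-1 linked matrix (0.0412), inflammatory (0.0412), glycolysis (0.0328) and exocrine acinar (0.0412) lists. The number lower was 7 after the GC and length correction, the numbers higher and lower 4 and 9 with sample weights, and the number higher 4 with DESeq2 without the earlier filter. With 1 library left out they ran from 2 to 6 higher and from 1 to 11 lower, the lowest number lower coming without Rosa26 gRNA replicate 3 or JunD gRNA replicate 1. On the 5 libraries they were 6 and 11 with edgeR, 6 and 11 with DESeq2, 7 and 10 with limma-voom, 5 and 11 after the correction, 6 and 11 with RLE and 5 and 11 with library totals.

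Whether the replicate numbers pair the samples could not be decided. Deviations from means of 3 libraries are dominated in the Rosa26 gRNA group by replicate 1, so a pairing could hardly show. Deviations from the group means of libraries with the same number had correlations across genes of 0.0555, -0.0393 and 0.0742. Replicates 1 and 3 of both groups correlated best with their own number. Rosa26 gRNA replicate 2 and JunD gRNA replicate 2 did not. With the replicate number as a block edgeR called 0 genes (2575 at an unadjusted p under 0.05, against 2119 without the block). Jund then had a log2 fold change of -0.463 (adjusted p = 0.319).

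Some named genes, none past the threshold with all 6 libraries, turned their direction, given here as log2 fold changes. Jun turned at -0.00211 (upper-quartile), -0.01 (totals only), -0.00223 (strict filter), -0.0944 (GC and length), -0.0501 (sample weights), on the 5 libraries -0.0126 (DESeq2), -0.0159 (limma-voom), -0.0337 (GC and length), -0.0119 (RLE), -0.0191 (totals only), and -0.0893 to 0.0698 with 1 library left out. Iapp turned at 0.00164 (limma-voom), 0.00309 (no filter), 0.00176 (replicate block), 0.156 (GC and length), and -0.111 to 0.0764 with 1 library left out. Txnip turned at 0.003 (no filter), 0.000384 (GC and length), and -0.0507 to 0.0343 with 1 library left out. Junb turned at -0.0838 (GC and length), and on the 5 libraries -0.0287 (GC and length). Fosl2 turned at 0.0187 (GC and length), 0.0184 (sample weights), on the 5 libraries 0.0199 (DESeq2), 0.0179 (limma-voom), 0.0488 (GC and length), 0.0199 (RLE), 0.013 (totals only), and -0.0532 to 0.0179 with 1 library left out. Pcsk1 turned at 0.0145 (GC and length). mt-Nd1 turned at 0.0307 (GC and length), and on the 5 libraries 0.0174 (GC and length). mt-Co1 turned at 0.0705 (GC and length), and on the 5 libraries 0.00573 (GC and length). Neat1 turned at 0.0773 (GC and length). Ddit3 turned at -0.0215 (sample weights), on the 5 libraries -0.021 (DESeq2), -0.0223 (limma-voom), -0.021 (RLE), -0.0279 (totals only), and -0.023 to 0.13 with 1 library left out.

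For each list, its direction and camera adjusted p with all 6 libraries are followed by the adjusted p under each setting that moved it across 0.05 or turned its direction. GC stands for the GC and length correction, weights for sample weights and totals for library totals. AP-1 family (lower, 0.197) came to 0.000506 (GC), 0.0334 (weights), on 5 libraries 0.0498 (DESeq2), 0.00121 (GC), 0.0409 (RLE), 0.0415 (totals) and ran from 0.0417 to 0.799 with 1 library left out. Immediate-early and MAPK feedback (higher, 0.97) turned at 0.999 (totals), 0.962 (strict filter), 0.025 (GC), 0.236 (weights), on 5 libraries 0.284 (DESeq2), 0.47 (voom), 0.00457 (GC), 0.178 (RLE), 0.165 (totals) and ran from 0.178 to 0.799 with 1 library left out, turning without Rosa26 1 or JunD 3. AP-1 linked matrix and adhesion (lower, 0.138) came to 0.00271 (GC), 0.0334 (weights), on 5 libraries 0.0115 (DESeq2), 0.0348 (voom), 0.000358 (GC), 0.00859 (RLE), 0.00927 (totals) and ran from 0.00903 to 0.522 with 1 library left out. Beta-cell identity and insulin (higher, 0.00186) came to 0.505 (estimated correlation), 0.099 (fry). Other islet hormones and their regulators (higher, 0.352) turned at 0.68 (weights), on 5 libraries 0.159 (DESeq2), 0.304 (voom), 0.0322 (GC), 0.164 (RLE), 0.165 (totals) and ran from 0.124 to 0.403 with 1 library left out, turning without Rosa26 1. Beta-cell disallowed and dedifferentiation (higher, 0.856) turned at 0.724 (GC), 0.857 (weights), on 5 libraries 0.707 (DESeq2), 0.758 (voom), 0.4 (GC), 0.722 (RLE), 0.709 (totals) and ran from 0.661 to 0.947 with 1 library left out, turning without Rosa26 1. Antioxidant response (higher, 0.0735) came to 0.0468 (voom), 0.0296 (no filter), 0.036 (replicate block), 0.0255 (DESeq2 unfiltered), on 5 libraries 0.0409 (voom) and ran from 0.0268 to 0.183 with 1 library left out. Pro-oxidant enzymes (lower, 0.0149) came to 0.118 (voom), 0.186 (no filter), 0.189 (DESeq2 unfiltered), 0.456 (estimated correlation), 0.0644 (fry) and ran from 0.00269 to 0.121 with 1 library left out. Endoplasmic reticulum stress (lower, 0.424) came to 0.0311 (GC), 0.00239 (weights), on 5 libraries 9.42e-05 (DESeq2), 0.000285 (voom), 0.000437 (GC), 0.00197 (RLE), 0.000824 (totals) and ran from 0.0015 to 0.92 with 1 library left out. Pro-apoptotic (lower, 0.988) turned at 0.969 (DESeq2), 0.947 (no filter), 0.634 (strict filter), 0.973 (replicate block), 0.933 (DESeq2 unfiltered) and ran from 0.48 to 0.951 with 1 library left out, turning without Rosa26 2, Rosa26 3 or JunD 1. Anti-apoptotic (lower, 0.97) turned at 0.925 (weights), on 5 libraries 0.711 (DESeq2), 0.758 (voom), 0.796 (RLE), 0.841 (totals) and ran from 0.815 to 0.97 with 1 library left out, turning without Rosa26 1 or JunD 1. Inflammatory and NF-kB response (lower, 3.97e-07) came to 0.145 (estimated correlation), 0.0644 (fry). Interferon response (lower, 0.665) came to 0.0334 (weights), on 5 libraries 0.0086 (DESeq2), 0.0104 (voom), 0.00103 (GC), 0.00859 (RLE), 0.00927 (totals) and ran from 0.00903 to 0.951 with 1 library left out, turning without Rosa26 2. The p53 and DNA damage response (lower, 0.218) came to 0.0154 (GC), 0.0328 (weights), on 5 libraries 0.0272 (DESeq2), 0.0348 (voom), 0.00402 (GC), 0.0334 (RLE), 0.0287 (totals) and ran from 0.0321 to 0.546 with 1 library left out. Cell cycle (higher, 0.305) came to 0.025 (GC), 0.0476 (weights), on 5 libraries 0.028 (DESeq2), 0.0374 (voom), 0.00103 (GC), 0.0409 (RLE) and ran from 0.0462 to 0.557 with 1 library left out. Cyclin and CDK inhibitor G1 control (higher, 0.424) came, on 5 libraries, to 0.018 (DESeq2), 0.0348 (voom), 0.0347 (GC), 0.0331 (RLE), 0.0359 (totals) and ran from 0.0321 to 0.646 with 1 library left out. Fatty acid oxidation and PPAR targets (higher, 0.777) turned at 0.849 (GC), on 5 libraries 0.996 (GC). Sterol synthesis (lower, 0.574) came to 0.0312 (weights), on 5 libraries 0.00512 (DESeq2), 0.0118 (voom), 0.00544 (GC), 0.0138 (RLE), 0.00927 (totals) and ran from 0.0121 to 0.968 with 1 library left out. Glycolysis (higher, 0.149) came to 0.0346 (weights), 0.0316 (DESeq2 unfiltered), on 5 libraries 0.02 (DESeq2), 0.0341 (voom), 0.0409 (RLE), 0.0473 (totals) and ran from 0.0412 to 0.286 with 1 library left out. Nuclear oxidative phosphorylation (higher, 1.62e-05) came to 0.505 (estimated correlation), 0.192 (fry). Mitochondrially encoded mRNA (lower, 0.116) came to 0.0194 (DESeq2), 0.0374 (voom), 0.0296 (no filter), 0.0143 (strict filter), 0.0188 (weights), 0.00218 (DESeq2 unfiltered), on 5 libraries 0.00208 (DESeq2), 0.000285 (voom), 0.0111 (RLE), 0.00927 (totals), turned at 0.547 (GC), on 5 libraries 0.0651 (GC) and ran from 0.011 to 0.311 with 1 library left out. Fibroblast and mesenchymal markers (higher, 0.672) turned at 0.947 (no filter), 0.835 (weights), on 5 libraries 0.993 (DESeq2), 0.843 (voom), 0.619 (GC), 0.924 (RLE), 0.985 (totals) and ran from 0.376 to 0.944 with 1 library left out, turning without Rosa26 1. Immune cell markers (lower, 0.939) turned at 0.549 (no filter), 0.659 (DESeq2 unfiltered) and ran from 0.699 to 0.971 with 1 library left out, turning without Rosa26 2. Endothelial markers (lower, 0.732) turned at 0.933 (DESeq2 unfiltered). Exocrine acinar markers (higher, 0.189) came, on 5 libraries, to 0.018 (DESeq2), 0.0149 (voom), 0.0131 (GC), 0.0111 (RLE), 0.0105 (totals) and ran from 0.011 to 0.217 with 1 library left out. Ductal markers (lower, 0.68) came, on 5 libraries, to 0.0035 (DESeq2), 0.0374 (voom), 0.00103 (GC), 0.00859 (RLE), 0.00927 (totals), turned at 0.825 (no filter), 0.947 (DESeq2 unfiltered) and ran from 0.00903 to 0.947 with 1 library left out, turning without Rosa26 2. RNA quality (lower, 0.424) came, on 5 libraries, to 0.018 (DESeq2), 0.0186 (voom), 0.0409 (RLE), 0.0409 (totals), turned at 0.547 (GC) and ran from 0.0412 to 0.855 with 1 library left out. Of the lists that turned, the immediate-early list passed as lower after the correction with 6 and 5 libraries, and the islet hormone list on 5.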

Other observations

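The tests of the 10 structural RNA and other genes, of GC content and length in Rosa26 gRNA replicate 1 and for Iqcn, and of other splits of the 6 libraries were chosen only after the result was seen.

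Iqcn, named after its values were seen and below the mean CPM required for ranking, rose by 2.77 ± 0.28 (SE) on the log2 scale without Rosa26 gRNA replicate 1 (edgeR adjusted p = 2.2e-06). Its counts were 43, 18 and 27 with the Rosa26 gRNA and 123, 120 and 177 with the JunD gRNA. It lies downstream of Jund on the same strand of chromosome 8, from 70703457 to 70717650 (GRCm38). A change of the whole region is argued against by the other 43 tested genes within 500 kb, whose median log2 fold change was 0.0989 with 0 past the threshold, and GC content and length by a log2 fold change of 2.21 after their correction with all 6 libraries. An effect of the JunD gRNA was not tested apart from these and stays open.

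Rosa26 gRNA replicate 1 lay 1.90 times as far from the other libraries as the most distant of them, by the median absolute log2 deviation. Counts taken up by the 10 structural RNA and other genes as the cause are argued against by their share of 1.67%, which shifts every other gene by -0.0214 on the log2 scale (-0.0217 to -0.021 against the other 5 libraries), far short of the excess of 0.144 in its median deviation. The fitted trend with GC content and length accounts for part. Its removal took the deviation from 0.303 to 0.195 and left a ratio of 1.72 (1.68 to 1.77 over 1000 resamples of genes). Genes are not independent, so this interval is too narrow. The removal also lowered the most distant other library, JunD gRNA replicate 3, from 0.159 to 0.113. Bias that the fit missed would remain, so the ratio cannot decide whether GC content and length are the whole cause. A JunD gRNA library under this label would be expected to lie nearer to the JunD gRNA libraries. For 82.4% of the genes called without it, this library lay nearer to the other Rosa26 gRNA libraries. Its own GC trend, opposite to that of the JunD gRNA libraries, could also place it there. The share was not recomputed after the GC and length correction, which kept 315 of the 523 calls. It therefore cannot decide the label by itself. RNA quality, rRNA depletion or another step of library preparation may be the source and stays open, and the labels give no batch.

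The nuclear oxidative phosphorylation list had a median log2 fold change of 0.0861 on the 5 libraries. Among 10000 random lists matched on GC content, length and expression it lay at percentile 99.84. The matched lists had a median of 0.0275 and a middle 95% from -0.00901 to 0.066. Their genes were drawn independently, whereas the list's members had an estimated correlation of 0.127. That range is therefore too narrow to decide by itself whether GC content and length are the whole cause. After the GC and length correction on the 5 libraries the list was still higher (camera adjusted p = 2.21e-07 at the preset correlation). That argues against the fitted trend as the whole cause, though bias that the fit missed would remain. An effect of the JunD gRNA may contribute, which is a hypothesis, since the list's call is lost with an estimated correlation.

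Other splits of the libraries are too few for a share under 0.05. With all 6 libraries, 10 of the 10 splits into 3 and 3 called as many genes as the real one, which called 0, and the highest other called 0. Since the real split called 0, every split had to call as many, so this count decides nothing. By unadjusted p under 0.05, which was not a planned measure, the real split had 2119 genes and the highest other 503. Without Rosa26 gRNA replicate 1, 1 of the 10 splits into 2 and 3 called as many as the real one, which called 523 genes, and the highest other called 9. By unadjusted p under 0.05 the real split of these 5 had 2908 genes, and the splits that set JunD gRNA replicate 3 with replicate 2 or 1 against the rest had 2225 and 1814.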
